A study of Mus musculus with 2 samples.

How the data were processed

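Left cerebral cortex of 2 male B6CASTF1/J mice was profiled by stranded total RNA sequencing with reduced ribosomal RNA and ERCC spike-ins, from 300 ng of RNA per library per the labels. The labels number the animals 2 and 4, and give them as biological replicates 1 and 2 of 1 group.

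Per the file headers, the authors deposited for each library a gene table and a transcript table with expected counts, TPM and FPKM on mm10 with the GENCODE M21 annotation, derived from alignments to the transcriptome. The same transcript tables hold each transcript's percent of its gene, per the file headers. A second deposited transcript table per library, derived from the reads themselves (2 read files for replicate 1 and 1 for replicate 2) per the notes deposited with the files, gives estimated counts and TPM. The programs, versions and settings are not given in the sources used here. Whether counting used the strand is also not given in the sources used here, so overlapping and antisense genes are uncertain, as are near-identical copies. Reads of the CAST genome were assigned against the mm10 reference, and any loss of reads by allele was not analysed here. The deposited TPM values sum over genes, 26248 tRNA entries, 96 spike-ins and 1 phiX entry. Effective lengths in the deposited tables equal the length minus 100 bases for 53134 of 55536 gene entries in the first quantification. In the second they equal, for long transcripts, the length minus 248 and 319 bases for replicates 1 and 2, so short RNAs are treated differently there in the 2 libraries.

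All 55536 gene entries matched the annotation, and 86 of them had no entry in the second quantification. Expected counts were rounded to whole numbers for library sizes and the coefficient of variation, and spike-ins, tRNA entries and 356 ribosomal RNA genes were left out of library sizes, which came to 24688669 and 27440152. The coefficient of variation between animals was estimated with edgeR 4.0.16 (intercept only, TMM scaling) over genes with a mean of at least 10 counts. Between-animal log2 ratios are replicate 1 over replicate 2 on TMM-scaled CPM with a prior count of 2, and genes with a mean of at least 50 normalised counts entered the count of 2-fold differences. List medians used genes with a mean of at least 10 counts and were placed among 10000 random lists drawn within 10 bins of expression. Ratios of lists used geometric means of TPM + 0.01. With 2 animals the smallest exact sign-flip p is 0.5, so no p-value is printed. Intervals of shares and count ratios are exact 95% binomial intervals, and the limit for a count of 0 is 3 counts. Both cover counting error only.

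The calculations were tested on simulated data. For a simulated coefficient of variation of 0.1 over 18284 genes, the estimate was 0.0992 with no changed genes and 0.152 with 200 genes changed 4-fold, so a few truly different genes raise it. All 200 changed genes, drawn from those with a mean of at least 200 counts, were recovered at 2-fold, with 3 unchanged ones. At a simulated coefficient of 0.2, 197 were recovered, with 285 unchanged ones. Recovery at lower counts was not simulated. Of 200 random lists of 10 genes, 7 fell outside the central 95%, and all 200 lay above the 97.5th percentile once a log2 shift of 0.5 was added. Lists of genes that vary together were not simulated.

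The gene lists, the rule for named genes, and the alternative settings were fixed before the data were examined. Named were the 15 genes with the highest mean TPM (spike-ins and ribosomal RNA left out), the 3 highest members and the lowest member of each list (receptor and channel families more fully), the 10 genes with the largest ratio in each direction, and isoform genes whose leading transcript differed or whose leading share was among the 5 largest. Some genes that this rule names are not reported here. Where 2 genes share a symbol, the one with the higher TPM was used. Alternatives covered DESeq2 1.42.0 size factors, spike-in scaling, other filters and prior counts, FPKM, log2(TPM + 1), the second quantification and each animal alone. R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used.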

Results

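Total RNA of the left cerebral cortex was sequenced from 2 adult male mice, aged 8 to 10 months, of the F1 hybrid strain B6CASTF1/J, a cross of B6 with Cast per the labels. The labels number the animals separately and place both in 1 group, so no condition was compared. Both carry the same donor label, so that they are distinct animals, on which every SD rests, is taken from the animal numbers alone. The libraries are called replicate 1 and replicate 2. They were made from 300 ng of RNA each, with ribosomal RNA reduced and ERCC spike-ins added, and held 26925514 and 30143684 expected counts. Values are given as TPM, a length-normalised transcript abundance, and ± marks the SD over the 2 animals throughout (n = 2). Coordinates are on mm10. The male label was matched by the sex chromosomes: Eif2s3y, Ddx3y and Uty, all on the Y chromosome, stood at 22.2 ± 2.55, 21.2 ± 2.09 and 12.9 ± 1.01 TPM, and Xist, the RNA of the inactive X chromosome, had 3 and 1 counts.

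A few short noncoding RNAs held much of the TPM, though not of the counts. The annotation class misc_RNA, which holds Rn7s1, Rn7s2 and Rn7sk, took 29.3% ± 2.02 of TPM. It took 3.86% ± 0.338 of the expected counts assigned to genes. The signal recognition particle RNA genes Rn7s1 and Rn7s2 (chromosome 12, 69159295 to 69159594 and 69361182 to 69361481) were listed at 128452 ± 10108 TPM each, with identical values in both files, so reads of these copies were shared between them. Their level was uncertain, since the second quantification listed each at 166414 and 34818 TPM in replicates 1 and 2. Rn7sk, the RNA that holds the elongation factor P-TEFb inactive (chromosome 9, 78175303 to 78175633), stood at 35800.1 ± 12.4 TPM. The second quantification listed Rn7sk at 51107 and 45489 TPM in replicates 1 and 2, so its level was uncertain as well. The RNase P RNA Rpph1 and the RNase MRP RNA Rmrp were listed at 5434 ± 611 and 3058 ± 504 TPM. These levels were uncertain too, since the second quantification gave Rpph1 6704 and 3619 TPM and Rmrp 6087 and 73.9 TPM. In the structured small RNA list, Rny3 had no counts in either library, where 3 counts correspond to 0.122 and 0.109 CPM. With genes annotated as ribosomal RNA left out, the 15 genes with the highest mean TPM also included Gm26917 (9552 ± 185 TPM) and Malat1 (4183 ± 428 TPM). Both are annotated as long noncoding RNAs, and whether Gm26917 holds reads of ribosomal RNA was not analysed here. The 15 also included 4 unprocessed pseudogenes that lie together on chromosome 1, Gm28661, Gm10925, Gm29216 and Gm28437. They stood at 7857 ± 1036, 5065 ± 739, 4813 ± 431 and 2843 ± 1257 TPM. The levels of these pseudogenes were uncertain, since the second quantification listed Gm29216 at 252 and 0 TPM and Gm28437 at 3694 and 7120 TPM.

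The 13 mRNAs encoded by the mitochondrial genome made up 3.04% ± 0.160 of all TPM. mt-Co1, a subunit of cytochrome c oxidase, led them at 7445 ± 687 TPM, ahead of mt-Co3 at 5306 ± 556 TPM, mt-Cytb at 3461 ± 356 TPM and mt-Nd1 at 2835 ± 438 TPM, and mt-Nd6 was lowest at 202 ± 10.8 TPM. The level of mt-Co3 was uncertain, since the second quantification listed it at 3333 and 5152 TPM in replicates 1 and 2. Any reads that these mRNAs share with near-identical copies elsewhere in the genome were not analysed here. The share of 3.04% thus covers only what was assigned to the mitochondrial entries. The 2 mitochondrial ribosomal RNAs added 10.7% ± 0.814 of all TPM. Nuclear genes of oxidative phosphorylation had a lower median, 174 ± 4.30 against 1788 ± 166 TPM, with Atp5b, a subunit of ATP synthase, at 853 ± 1.99 TPM, Cox4i1 at 520 ± 2.34 TPM, Atp5a1 at 358 ± 10.6 TPM and Ndufs1 lowest at 72.8 ± 3.95 TPM. Protein-coding genes took 81.9% ± 0.375 of the expected counts assigned to genes. At least 1 TPM in both animals was reached by 15028 of 55536 genes, 12994 of them protein coding. ERCC spike-ins took 0.261% of all expected counts in replicate 1 (exact 95% binomial interval 0.259 to 0.263) and 0.275% in replicate 2 (0.273 to 0.277). These intervals cover counting error only.

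Genes of neurons stood far above the spread between animals. Snap25 and Syp, proteins of synaptic vesicle release, reached 1258 ± 44.1 and 908 ± 57.9 TPM, and Nefm was the lowest pan-neuronal gene at 66.3 ± 3.46 TPM. Among excitatory neuron genes, the kinase Camk2a stood at 1058 ± 27 TPM, Nrgn at 628 ± 34.6 TPM, the vesicular glutamate transporter Slc17a7 at 455 ± 20.2 TPM and Emx1 at 12.3 ± 3.35 TPM. Among inhibitory neuron genes, the GABA-synthesising enzymes Gad1 and Gad2 stood at 245 ± 24.3 and 70.9 ± 3.29 TPM and Dlx5 at 4.45 ± 0.530 TPM. The ratio of Slc17a7 to the sum of Gad1 and Gad2 was 1.44 ± 0.0620. By the geometric means of the whole lists, the ratio of excitatory to inhibitory genes was 2.68 ± 0.00229. Of the interneuron subclass genes, Cck, Sst and Lamp5 led at 244 ± 10.5, 192 ± 9.49 and 95.1 ± 0.219 TPM, and Sncg was lowest at 2.04 ± 0.849 TPM. All 10 of these genes held the same order in both animals.

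Genes of upper and deep cortical layers were both present. Rasgrf2, Cux2 and Calb1 led the upper-layer list at 86.2 ± 2.41, 70.2 ± 2.85 and 52.3 ± 5.39 TPM, and Scnn1a was lowest at 1.35 ± 0.0495 TPM. Bcl11b, Crym and Etv1 led the deep-layer list at 45.1 ± 1.17, 44.6 ± 1.64 and 30.8 ± 2.20 TPM, and Ntsr1 was lowest at 3.16 ± 0.297 TPM. The ratio of the geometric means of the lists was 1.20 ± 0.0793.

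Glial genes followed the order astrocyte, oligodendrocyte, microglia and oligodendrocyte precursor by list median, at 71.2 ± 0.226, 70.7 ± 6.92, 17.1 ± 0.682 and 9.28 ± 0.742 TPM; the first 2 differed by less than the spread. The glutamate transporter Slc1a2 led the astrocyte list at 804 ± 22.4 TPM, ahead of Aldoc at 347 ± 18.9 TPM and Slc1a3 at 144 ± 13.95 TPM. The myelin genes Mbp and Mobp stood at 929 ± 33.6 and 216.7 ± 4.25 TPM, and Opalin at 6.38 ± 2.72 TPM. The ratio of oligodendrocyte to pan-neuronal genes, by geometric means, was 0.235 ± 0.0119. Olig1, Pdgfra and Sox10 of the precursor list stood at 41.2 ± 2.23, 16.2 ± 2.97 and 14.2 ± 0.120 TPM. Microglial Csf1r and C1qb stood at 36.5 ± 1.53 and 23.7 ± 0.240 TPM. Among reactive glia genes, the lipid carrier Apoe stood at 798 ± 9.86 TPM, the astrocyte filament Gfap at 61.4 ± 0.318 TPM and B2m at 49.5 ± 1.75 TPM, while Cst7 had no counts. The interferon response list was low, with Ifi27 at 38.0 ± 1.68 TPM and Usp18 at 0.31 ± 0.255 TPM.

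Vascular and blood genes were present as well. The glucose transporter Slc2a1, Ly6c1 and Itm2a led the endothelial list at 43.5 ± 5.28, 32.4 ± 3.70 and 21.9 ± 4.31 TPM. Vtn, Rgs5 and Pdgfrb led the mural list at 34.4 ± 2.01, 19.6 ± 1.51 and 6.39 ± 1.28 TPM. Ptgds, prostaglandin D synthase, stood at 989 ± 43.4 TPM in the vascular leptomeningeal list, where Lum was lowest at 1.21 ± 0.0636 TPM. The haemoglobin genes Hba-a1, Hbb-bs and Hba-a2 stood at 167 ± 32.7, 166 ± 37.3 and 147 ± 45.6 TPM, and copies of these genes share reads. The blood leukocyte and border macrophage list was led by Pf4, Mrc1 and Ptprc at 1.81 ± 0.856, 1.73 ± 0.290 and 1.46 ± 0.106 TPM.

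Markers of other brain regions were set beside the cortical layer lists, whose medians were 18.3 ± 0.675 TPM (upper) and 14.3 ± 1.10 TPM (deep). The striatal list had a higher median than both, 54.3 ± 3.67 TPM. It was led by Ppp1r1b, the dopamine-regulated phosphatase inhibitor, at 273 ± 20 TPM. The enkephalin precursor Penk stood at 186 ± 13.9 TPM, the phosphodiesterase Pde10a at 111 ± 2.12 TPM, and Rarb was lowest at 17.5 ± 0.156 TPM. Whether striatal tissue was in the dissections was not tested. The excitatory to inhibitory ratio and the layer lists therefore describe the tissue as dissected, which may not be cortex alone. The hippocampal, thalamic, olfactory bulb and cerebellar lists had medians of 2.29 ± 0.0672, 5.05 ± 0.919, 1.73 ± 0.771 and 0.215 ± 0.0354 TPM. Their highest members were Trpc6 at 9.75 ± 0.0566 TPM, Ramp3 at 8.20 ± 0.962 TPM, Cdhr1 at 8.26 ± 1.97 TPM and Cbln1 at 4.68 ± 0.0424 TPM. Gabra6, a GABA-A receptor subunit of cerebellar granule cells, had no counts in either library.

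**Figure D1:**
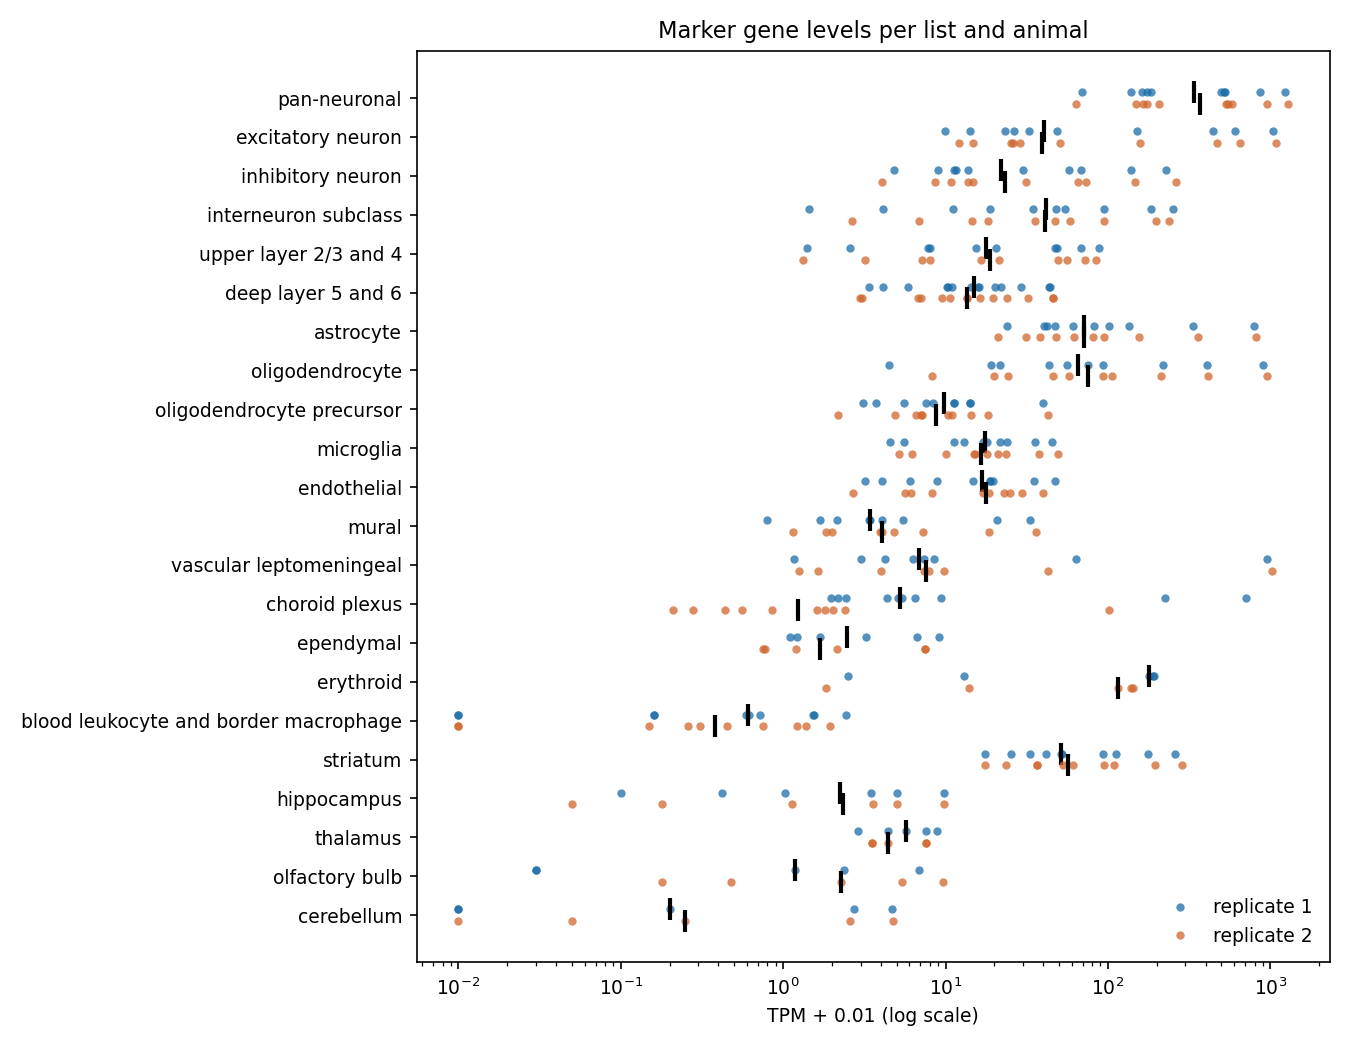
Levels of the marker genes of each list as TPM + 0.01 on a log axis, with 1 point per gene and animal (blue, replicate 1; orange, replicate 2) and a black tick at each list's median. The animals overlap in most lists, while the choroid plexus median is 5.26 TPM in replicate 1 and 1.23 TPM in replicate 2.

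Subunits of the ionotropic glutamate receptors differed from one another by more than the spread between animals in most cases. Of the AMPA receptor, Gria2 was highest at 211 ± 5.46 TPM, then Gria1 at 129 ± 4.72 TPM, Gria3 at 91.8 ± 7.90 TPM and Gria4 at 42.0 ± 2.97 TPM. Of the NMDA receptor, the obligatory subunit Grin1 stood at 171 ± 11.8 TPM, Grin2b and Grin2a at 110 ± 6.21 and 108 ± 9.28 TPM, which did not differ beyond the spread, and Grin2c, Grin3a and Grin2d at 16.2 ± 0.856, 14.5 ± 0.573 and 4.87 ± 0.332 TPM. Grik5 led the kainate receptor list at 87.1 ± 8.38 TPM, before Grik2 at 38.6 ± 4.53 TPM and Grik3 at 27.02 ± 0.339 TPM, with Grik1 lowest at 7.63 ± 1.80 TPM. Of the metabotropic receptors, Grm5 stood at 91.5 ± 8.97 TPM, Grm3 at 61.5 ± 4.07 TPM and Grm7 at 34.5 ± 0.693 TPM, and Grm6 had no counts.

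Of the GABA-A receptor, Gabrb2 stood at 89.6 ± 5.52 TPM. The pore-forming sodium channel subunits Scn2a, Scn8a, Scn1a and Scn3a stood at 140 ± 9.78, 99.2 ± 6.68, 54.4 ± 0.679 and 14.4 ± 0.0849 TPM. Of the potassium and HCN channels, Hcn2 stood at 73.1 ± 3.14 TPM and Hcn4 at 2.17 ± 0.0495 TPM. Of the calcium channels, Cacna1a, Cacna1e and Cacna1b stood at 90.8 ± 3.52, 71.1 ± 4.33 and 36.6 ± 2.60 TPM. Among monoamine, acetylcholine and cannabinoid receptors, Chrm1 and Cnr1 stood at 62.6 ± 0.863 and 62.4 ± 2.52 TPM, Drd1 at 39.0 ± 3.70 TPM and Drd5 at 1.23 ± 0.0990 TPM.

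**Figure D2:**
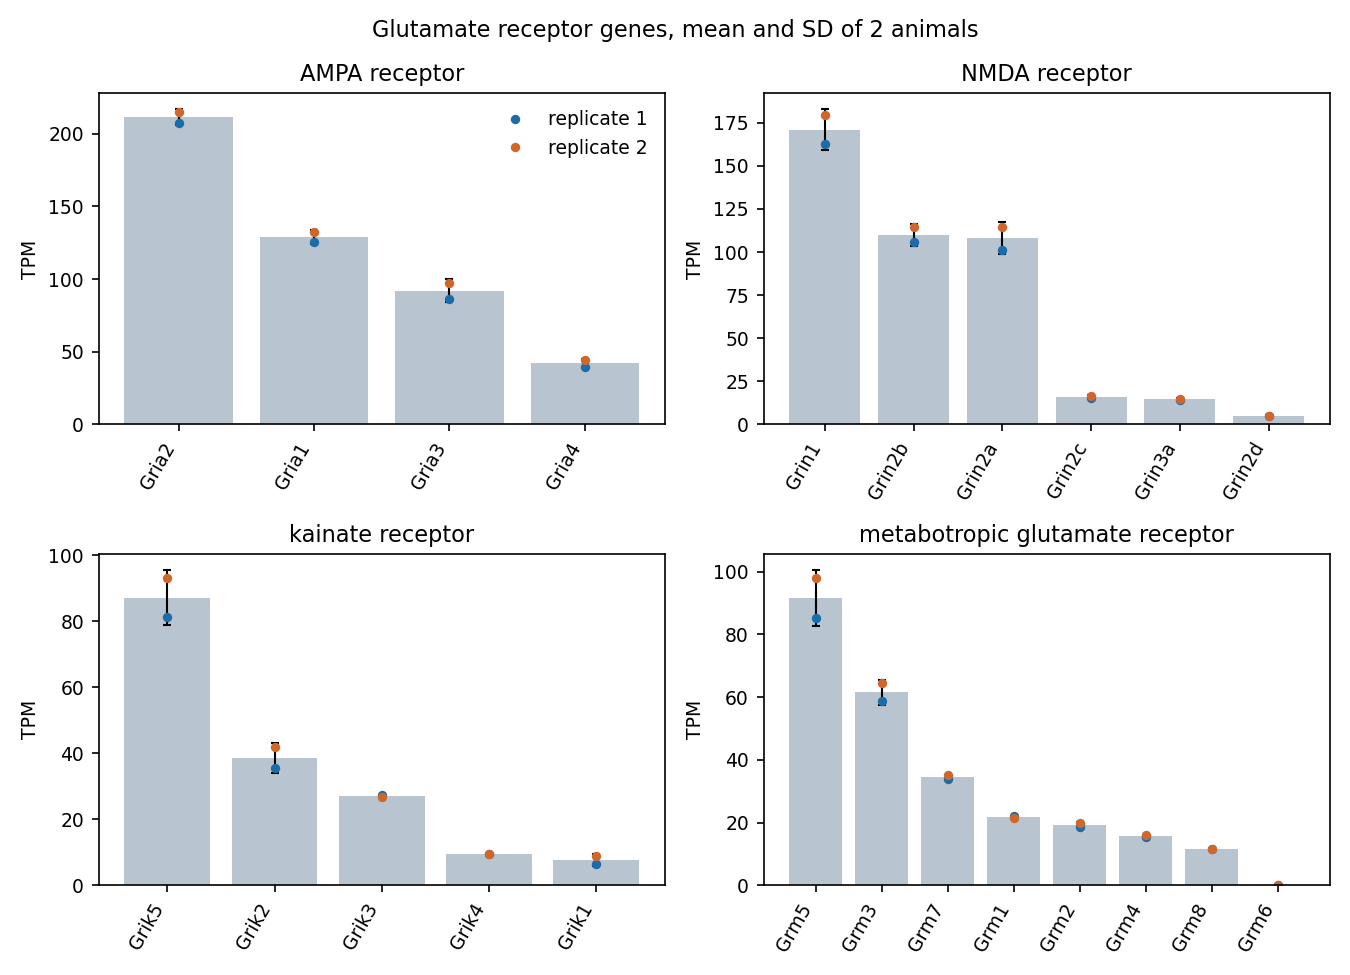
Levels of AMPA, NMDA, kainate and metabotropic glutamate receptor genes in TPM on linear axes from 0. Bars are means, error bars the SD of 2 animals, and points the animals (blue, replicate 1; orange, replicate 2); Gria2 at 211 TPM, Grin1 at 171 TPM, Grik5 at 87.1 TPM and Grm5 at 91.5 TPM are the highest of their lists.

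Among neuropeptides and granins, Cck, Sst and the enkephalin precursor Penk were highest and Cort was lowest at 3.42 ± 0.530 TPM. Imprinted genes, expressed mainly from 1 parental allele, were led by Meg3 at 968 ± 106 TPM, Gnas at 801 ± 16.1 TPM and Rian at 493 ± 40.8 TPM, while H19 stood at 0.220 ± 0.0990 TPM. The files give totals over both alleles, and the alleles were not analysed here. The long noncoding RNA list was led by Malat1, Meg3 and Snhg14 (766 ± 93.2 TPM), with Kcnq1ot1 lowest at 3.03 ± 0.304 TPM. Of genes linked to neurodegeneration, Apoe, the amyloid precursor gene App and the prion gene Prnp stood at 798 ± 9.86, 629 ± 11.96 and 384 ± 11.99 TPM and Trem2 at 5.36 ± 1.19 TPM. Replacement histone genes exceeded the replication-dependent ones by a factor of 4.17 ± 0.163 in geometric mean, with H3f3a at 134 ± 2.36 TPM and Hist1h4d at 59.9 ± 0.799 TPM as the highest of each.

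The 2 animals were then set against each other. Across 18284 genes the coefficient of variation between them was 0.109, and the median absolute difference among 14162 genes with a mean of at least 50 normalised counts was 1.08-fold. Of these, 121 genes differed at least 2-fold, 78 higher in replicate 1 and 43 higher in replicate 2, and 77 did so in the same direction by both quantifications. With 1 library per animal there is no test of a single gene, and the differences have no replicate check. For each of 47 lists, the median log2 ratio of replicate 1 over replicate 2 was set among 10000 random lists matched on expression. This gave 15 lists outside the central 95%, against 2.35 expected at random, as a description of these libraries. The 2.35 holds for lists of unrelated genes, whereas members of these lists can vary together and some are in more than 1 list.

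Choroid plexus genes, of the epithelium that makes cerebrospinal fluid, were higher in replicate 1. All 10 members were at least 2-fold higher, with a median log2 ratio of 2.41 (5.33-fold; random lists -0.18 to 0.14). Ttr, the thyroid hormone carrier transthyretin (chromosome 18, 20665280 to 20674321), stood at 711 TPM in replicate 1 and 2.40 TPM in replicate 2, a log2 ratio of 8.20 with a counting interval of 232-fold to 413-fold. Enpp2, which makes lysophosphatidic acid, stood at 225 and 101 TPM, Kl at 9.39 and 1.60 TPM and Slc4a5 at 184 and 4 counts. Mfrp and Sostdc1 were also among the 10 genes most raised in replicate 1, with log2 ratios of 5.03 and 4.81 (3.83 and 4.86 by the second quantification). So was 1500015O10Rik, with 131 and 3 counts, a log2 ratio of 4.87 and a counting interval of 16.5-fold to 242-fold. The ependymal list, of ciliated cells that line the ventricles, had a median log2 ratio of 0.43 (random lists -0.48 to 0.41).

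Immediate early genes, which respond to neuronal activity within minutes, were higher in replicate 1 for 14 of 14 members, 8 of them at least 2-fold, with a median log2 ratio of 1.14 (random lists -0.07 to 0.10). Arc (chromosome 15, 74669083 to 74672570) stood at 163 TPM in replicate 1 and 27.8 TPM in replicate 2, Egr1 at 100.3 and 59.5 TPM, Egr3 at 70.7 and 58.6 TPM and Ier2 at 6.75 and 2.72 TPM. Heat shock genes were higher in replicate 1 for 6 of 6 members (median log2 ratio 0.44), with Hspa8 at 1031 and 782 TPM, and glucocorticoid-responsive genes for 8 of 8 (0.37), with Tsc22d3 at 55.8 and 40.6 TPM. The erythroid list had a median log2 ratio of 0.52, with 4 of 5 members higher in replicate 1. The circadian clock list stayed inside the random range at 0.07, with Per1 at 70.0 and 48.0 TPM and Dbp at 51.1 and 75.5 TPM.

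Smaller shifts left the random range in 8 further lists. Structured small RNAs (0.21), endothelial genes (0.13) and neuropeptides and granins (0.09) had positive medians, while mural genes (-0.19), mitochondrially encoded mRNAs (-0.14), kainate receptors (-0.11), GABA-A receptors (-0.08) and long noncoding RNAs (-0.06) had negative ones. The structured small RNA median is the value of Rn7s1 and Rn7s2, copies that share reads. By the second quantification the endothelial list lay inside the random range, at percentile 97.1. On log2(TPM + 1) the endothelial, mural, GABA-A receptor and long noncoding RNA lists lay inside it, at percentiles 95.2, 8.82, 10.8 and 5.58. By the second quantification the medians of structured small RNAs, mitochondrially encoded mRNAs and long noncoding RNAs were 0.79, -0.061 and -0.039. The 0.79 is the value of Rpph1, and effective lengths there treated short RNAs differently in the 2 libraries. Of 27 genes with lengths between the 2 lengths subtracted there, 10 were 2-fold higher in replicate 1 and 0 in replicate 2. Of 66 longer genes of up to 400 bases, 16 and 1 were. By the first quantification 2 and 6 genes of these groups differed 2-fold in either direction. The 0.79 is thus no separate evidence on the animals. With scaling by the spike-ins, which moved the median of all genes to 0.07, that of the long noncoding RNA list became 0.0033 and so stayed lower than it. The olfactory bulb list was lower in replicate 1 for 4 of 4 counted members, with a median log2 ratio of -0.92, at low levels such as Doc2g at 2.37 and 5.39 TPM.

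The genes most raised in replicate 2 included Tnnt3, Myh6, Atp2a1 and Myh4, which encode troponin T, myosin heavy chains and a calcium pump of striated muscle. Their log2 ratios of replicate 1 over replicate 2 were -2.34, -1.95, -1.88 and -1.76, at no more than 6.55 TPM. The overlapping gene Gm20517 had a log2 ratio of -1.83. Many of the largest ratios in both directions belonged to near-identical copies, overlapping genes and short RNAs. Gm12671, Gm10240 and Gm13370 had 167, 153 and 153 counts in replicate 1 and none in replicate 2. Gm13394, Gm10359 and Gm5559 had 746, 285 and 143 counts in replicate 2 and none in replicate 1, and Gm6361 had 214 and 1. Gm10240, Gm13370, Gm13394, Gm5559 and Gm20517 differed at least 2-fold in the same direction by the second quantification too. Gm5559 had only 0 and 5.40 estimated counts there, however, and Gm13394 5.42 and 38.7. Gm10240 and Gm13370 had identical values in both quantifications, so reads of these copies were shared. For all of these genes the deposited TPM intervals, whose level is not given, overlapped between the libraries, so these assignments are uncertain. Other assignments are uncertain: Gm20388 had 0 and 528 counts but a log2 ratio of -0.012 by the second quantification. In that quantification 1700047I17Rik2 and Gm24497, with 294 and 1051 counts in replicate 1 and 0 and 9 in replicate 2, were at 0. Gm12671, Gm10359 and Gm6361 were also at 0 there in both libraries.

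**Figure D3:**
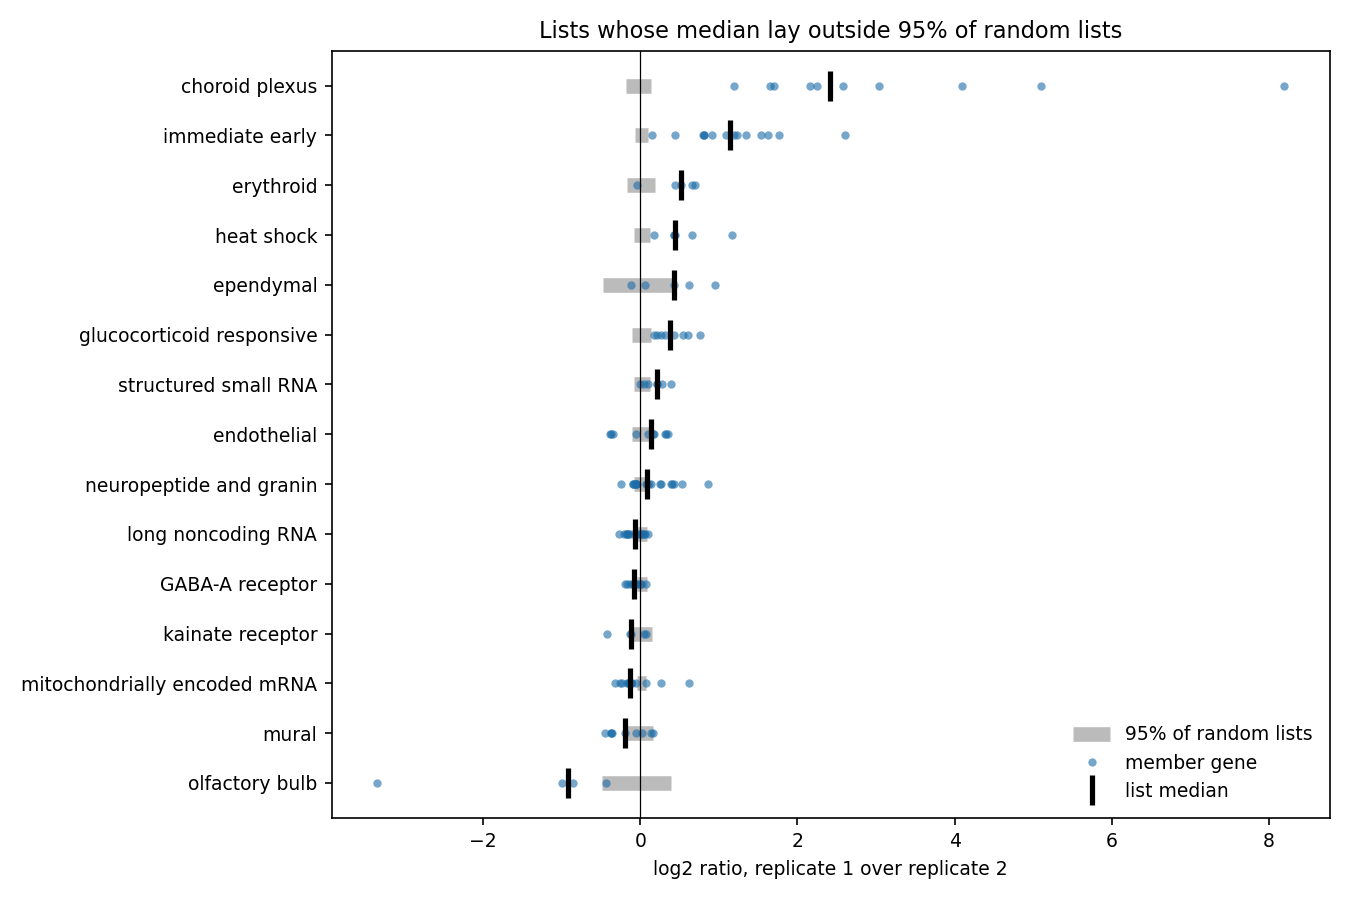
Log2 ratio of replicate 1 over replicate 2 for the 15 lists outside the central 95% of random lists. Blue points are genes, black ticks list medians and grey bars the central 95% of random lists; choroid plexus (2.41) and immediate early genes (1.14) lie farthest to the right and the olfactory bulb list (-0.92) farthest to the left.

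Transcript choice was compared between the quantifications for 30 genes. The most abundant transcript was the same for 27. By the first quantification, App, Snap25, Camk2b, Clta and Cltb had the largest shares of a gene's TPM in 1 transcript. These were 90.4% ± 0.109, 89.3% ± 0.838, 86.7% ± 0.398, 76.4% ± 1.26 and 75.3% ± 1.31. By the second, the leading transcript of Clta held 61.3% ± 1.55, below that of Camk2a at 71.6% ± 4.69. For Grin1 and Nrcam, among others, the most abundant transcript differed between the quantifications, so their leading isoform was left open. In the first quantification, the leading transcript was the same in both animals for 27 of the 30 genes.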

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

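Reads outside the gene measurements were present in both libraries. The phiX control sequence had 75 counts in replicate 1 and 55 in replicate 2, and tRNA entries summed to 5.89 counts in replicate 2. Each count was above 3, the highest mean that an observed count of 0 allows.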

How the results depend on the processing

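The alternative that required both quantifications was chosen after the data were seen; the cause of each move was not tested unless stated. The mitochondrial share moved to 1.84% in expected counts, 3.41% in the second quantification and 13.7% with the 2 ribosomal RNAs, which adds genes. The spike-in share was 0.568% in TPM and 0.226% in the second quantification. The excitatory to inhibitory ratio was 2.68 from list means and 1.78 in the second quantification, and the oligodendrocyte to pan-neuronal ratio 0.199 from medians and 0.208 from expected counts. The coefficient of variation was 0.0945 with at least 100 counts and 0.129 in the second quantification. Genes differing 2-fold numbered 33 with at least 200 counts, 2910 with no filter (low counts are noisy), 78 on log2(TPM + 1) and 77 in both quantifications. The long noncoding RNA shift became 0.0033 with spike-in scaling, which moved the median of all genes alike, from 0.0065 to 0.072, so the sign follows from the scaling. Counts of detected genes, shifted lists (15, but 11 on log2(TPM + 1), without the endothelial, mural, GABA-A receptor and long noncoding RNA lists) and matching isoforms stayed within 1.5 times. The 15 lists by the second quantification were not the same: the endothelial list left (percentile 97.1) and the thalamus list entered (98.1). With 2 animals, each alone always lies within 1 SD of their mean, so leaving 1 out says nothing about stability. Levels of named genes moved by over 1 SD for 110 of 211 genes in the second quantification, 78 higher and 32 lower, where Rmrp, a short RNA, had 6087 and 73.9 TPM.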

Other observations

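The tests of spike-in scaling and of the clock genes already in the fixed list were chosen after their results were seen; the others were set before the values that decide them were seen, although the choroid plexus list and Ttr, on which the tests of read assignment and liver RNA rest, had been seen in the first quantification. Chosen after their values were seen, 2 chaperones of the endoplasmic reticulum were higher in replicate 1: Hspa5 at 225 and 103 TPM and Sdf2l1 at 17.65 and 6.27 TPM. Of the steroid synthesis genes of the adrenal gland, Hsd3b1 had 43 and 0 counts, Cyp21a1 33 and 0 and Cyp11b1 19 and 1, while Star had 57 and 44 and Cyp11a1 42 and 37.

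Choroid plexus genes were higher in replicate 1. The tables argue against liver RNA, since the ratio of Alb to Ttr in replicate 1 was 4.22e-05, and against read assignment by 1 quantification, since the list median was 2.27 in the second. Choroid plexus tissue in the dissection may account for the pattern: 14 further choroid plexus genes had a median log2 ratio of 1.29 (quartiles 0.44 and 1.90). All 14 ratios were above 0, but that of Slc13a4 was only 0.0024, and Lmx1a had 3 and 0 counts. Of the 14 genes, 9 also had at least 10 counts in replicate 2. The design names no group that differs, so it gave no biological explanation to test.

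Immediate early genes were higher in replicate 1. Scaling by the spike-ins left the difference in place, with a list median of 1.21. That scaling moves all genes alike, so its outcome followed from the scaling factors and is no separate test of this list. A wider activity-dependent programme was shifted as well: 20 further activity-dependent genes had a median log2 ratio of 0.69, all 20 higher in replicate 1. These genes are of the same kind as the list, so they widen the pattern and do not tell its cause. A different time of day stays open, because clock output genes minus opposite-phase genes gave -0.42 on genes already seen, which cannot count in its favour, while 4 clock genes not examined before gave -0.054, inside the random range of -0.10 to 0.16. What differed in the handling of the animals was not analysed here.

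Striated muscle genes were higher in replicate 2. Skeletal muscle tissue or RNA may account for it, since 15 further skeletal muscle genes had a median log2 ratio of -1.26, all 15 lower in replicate 1. Reads from a heart library remain open as well. The 13 heart genes had a median log2 ratio of -1.18, with 11 lower in replicate 1 and 1 higher. In replicate 2, 8 of the 13 had 10 or more counts, although 4 of these also did in replicate 1, and Myl7 had 0 counts in both libraries. The skeletal muscle and heart sets moved in the same direction, so they do not tell these 2 sources apart. Reads from several other organs could be neither excluded nor favoured. The 8 adrenal genes other than Chga, which the cortex also expresses, summed to 92.2 counts in replicate 2 and 201 in replicate 1. Star and Cyp11a1 held 44 and 37 of the replicate 2 counts, against 57 and 42 in replicate 1. Dbh (1 and 4 counts in replicates 1 and 2) and Pnmt (3 and 6) were higher in replicate 2. The sum thus showed no excess of adrenal reads in replicate 2, and it does not cover other organs. The design gave no biological explanation to test.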
